A study of Peniophora incarnata with 12 samples.

How the data were processed

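The deposited file held, for each of 16059 genes, the FPKM of 12 libraries that the authors had computed before deposit, with gene descriptions, symbols and pathway names. Per the submitters' processing notes the tools were fastp, HISAT2, HTSeq and DESeq2, with no versions or roles stated. The genome build is not given in the sources used here. Strandedness of the libraries was taken from the kit named by the submitters. Gene counts, read files and the duplication modes of genes were not analysed here. Of the 16059 genes, 8356 had a description and 8232 a symbol, and 2925 a pathway name. Among the 13974 tested genes 7706 had a description.

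FPKM values are fractions of whole reads, so the reads of each gene and the total of each library were worked back from the smallest steps between the values of a gene and from gene lengths being whole numbers of bp. Whole reads within 0.001 were found for 16059 of 16059 genes. In a simulated file the totals of 12 of 12 libraries were recovered. The recovered totals were 23398461 to 31132066 reads, and the median coding length was 1410 bp. These reads served for the depth statements and for the alternatives that need counts.

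The design, the gene lists and all alternatives except voom and the omission of the intermediate libraries were fixed before the data were examined. The values were taken as log2(FPKM + 1), and genes were kept at 1 FPKM or more in at least 3 libraries. One limma fit of the 4 groups with eBayes and a mean-variance trend gave the pairwise contrasts, the contrast of the 3 substrates with PDA, and the F test among the 4 groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes with an absolute log2 fold change of at least 1. "Adjusted over the list alone" means the same rule with the adjustment over the members of 1 list. Where that wording is not given beside a list in the report, the counts were the same both ways. Standard errors are those of limma, from 1 spread per gene shared by the 4 groups. Groups did not overlap where every library of 1 group lay above every library of the other. In the self-test for poplar wood against PDA, an adjusted p alone found 62.5% of 40 genes raised by 1 on the log2 scale, 100% raised by 2, 45% lowered by 1 and 95% lowered by 2. It called 9 of 13509 unchanged genes. All simulated groups had the same spread, unlike the real poplar wood libraries, so these rates need not hold for comparisons with poplar wood.

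Gene lists were built by fixed patterns on descriptions, and 33 of 37 lists with at least 5 tested members were tested. Of the other 4 lists, 2 had no members and 2 had fewer than 5. The list of cytosolic ribosomal proteins left out mitochondrial proteins, and the list of transcription factors left out general initiation and elongation factors. Lists could share members. Each list was tested by camera with the preset correlation of 0.01 and adjusted over the lists of a comparison, then with a correlation estimated from the residuals, and by fry. Camera called 9, 9, 15, 7, 8 and 8 lists for poplar wood against PDA, Chinese fir wood against PDA, rice straw against PDA, poplar wood against Chinese fir wood, poplar wood against rice straw, and Chinese fir wood against rice straw. Fry called 19, 24, 17, 21, 16 and 20. Summed FPKM of 9 enzyme lists were compared by exact permutation over all splits of the 12 libraries into 9 and 3. No sum passed after adjustment, and 0 passed in TPM or without the most abundant member.

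Genes named in the report were picked by a fixed rule. Against PDA these were the 8 largest rises and the 8 largest falls among called genes with a mean of at least 10 FPKM in the higher group, groups that did not overlap and an informative description. The most abundant called member of each list that rose and that fell was added. Between substrates the rule took 4 and 4 with the same additions, and for the shared response 5 and 5 with the largest minimum change. The report names a subset.

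Libraries were not paired across groups by replicate number. Alternatives tried were a pseudocount of 0.1 or 5, no fold threshold, no filter on low values, a filter at 5 FPKM in 3 libraries, a fit of only the 2 groups compared, TPM, median-of-ratios and quantile scaling, array weights, replicate number as a block, voom on the worked-back reads, leaving out each library in turn, and leaving out the 3 intermediate libraries. Median-of-ratios scaling divided the FPKM of each library by the median ratio to the geometric mean over genes above 0 in every library. The array weights did not reach the convergence tolerance. The limit on shared responses is that all 3 contrasts use the same PDA libraries, and the overlap was compared with independent lists and with simulated unchanged groups. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.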

Results

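Peniophora incarnata is a white-rot basidiomycete, a fungus that degrades the lignin and the polysaccharides of wood. Gene expression was measured by stranded mRNA sequencing in mycelium of its strain T-7 after 30 days of growth on powdered poplar wood, Chinese fir wood or rice straw, or on PDA, a potato dextrose agar medium that served as the control. Each of the 4 groups had 3 biological replicates. Hardwood, softwood and grass were each represented by a single material, so a difference between materials cannot be assigned to the class of plant. The values were FPKM of 16059 genes, and 13974 genes that reached 1 FPKM in at least 3 of the 12 libraries were tested. The reads behind the FPKM values numbered 25804766, 23398461 and 25527090 on poplar wood (replicates 1, 2 and 3), 31132066, 28171813 and 23936783 on Chinese fir wood, 26457346, 27057927 and 30952888 on rice straw, and 24075495, 24766171 and 25570109 on PDA. For a gene of the median coding length of 1410 bp, 1 read was worth 0.0228 to 0.0303 FPKM, so that a level of 1 FPKM rested on 33.0 to 43.9 reads. Gene names and descriptions below are those of the best database match given with the data, and fold changes are differences of log2(FPKM + 1), which understate the change of genes with low FPKM.

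The libraries separated by substrate. Of the 13974 genes, 10338 differed among the 4 groups by the limma F test at an adjusted p of 0.05. The first principal component held 35.8% of the variance and the second 30.4%. Correlations between libraries of a group were 0.971 to 0.988 on PDA, 0.967 to 0.988 on Chinese fir wood and 0.977 to 0.989 on rice straw. On poplar wood they went down to 0.865. The median SD of a gene was 0.46 on the log2 scale there, against 0.15 on PDA, 0.19 on Chinese fir wood and 0.18 on rice straw. In the fit each gene had 1 spread shared by the 4 groups. For a typical gene the standard errors and p-values of poplar wood comparisons therefore understate the spread on poplar wood, and the other comparisons carry part of it. Poplar wood replicate 1 correlated at 0.926 with poplar wood replicate 2 and at 0.865 with replicate 3, and at 0.877, 0.897 and 0.849 with replicates 1, 2 and 3 of Chinese fir wood. Replicate 1 of Chinese fir wood, replicate 3 of rice straw and replicate 2 of PDA lay close to a weighted sum of the reads of the other libraries of their groups, with a chi-square per gene of 5.75, 7.51 and 4.92, while the other libraries of these groups gave 23.6 to 47.3. These 3 libraries are called the intermediate libraries, and calls over all genes are also given without them. List counts of at least 3 are given without them where they changed by more than 1.5 times or where the list is discussed at length.

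**Figure D1:**
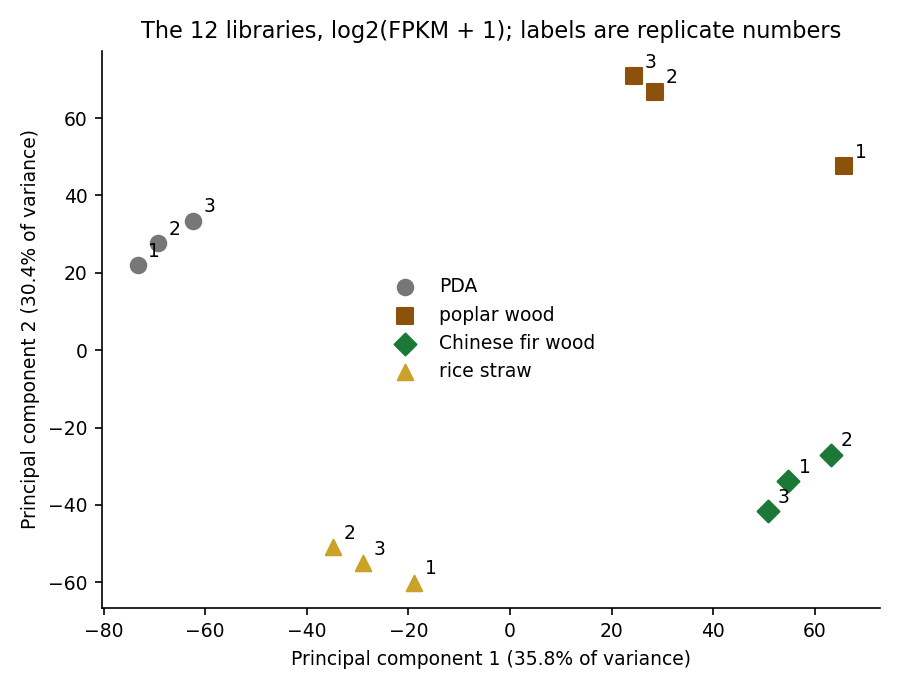
Scores of the 12 libraries on the first (35.8% of the variance) and second (30.4%) principal components of log2(FPKM + 1) over 13974 genes, labelled with replicate numbers. The poplar wood libraries lie farther apart than those of the other groups.

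Growth on poplar wood was compared with growth on PDA to describe the response to a hardwood. Lignin-modifying enzymes were among the genes with the largest rises, and phosphoketolases and an isocitrate lyase among those with the largest falls. The laccase LCC2 (A15469), an oxidase of phenolic compounds, had 6.89 ± 3.72 FPKM on PDA and 442 ± 437 FPKM on poplar wood (SD, n = 3 each), a log2 fold change of 5.50 (SE 0.56, adjusted p = 1.83e-05). The versatile peroxidases VPL1 (A19457) and VPS1 (A14046), which oxidise lignin units and manganese, rose by 5.46 to 138 ± 159 FPKM and by 4.67 to 87.2 ± 96.7 FPKM. The isocitrate lyase ACU-7 (A18288) and the malate synthase acuE (A01812), the enzymes particular to the glyoxylate cycle, had log2 fold changes of -4.80 and -4.75. Another isocitrate lyase, ICL1 (A09090), named after its values were seen, was not called (log2 fold change -0.36, adjusted p = 0.522). A second gene named ICL1 (A06133), also given after its values were seen, stood at 25.6, 16.1 and 9.98 FPKM in poplar wood replicates 1, 2 and 3. On PDA it stood at 130, 248 and 345 FPKM. The poplar wood libraries differed widely in level: LCC2 stood at 946, 191 and 188 FPKM and VPL1 at 26.6, 320 and 67.4 FPKM in replicates 1, 2 and 3. Leaving out poplar wood replicate 1 changed the log2 fold changes of LCC2, VPL1, VPS1 and acuE to 4.73, 6.26, 5.40 and -3.72. Leaving out replicate 2 changed those of VPL1, VPS1, ACU-7 and acuE to 4.49, 3.77, -5.56 and -5.64.

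Of the 23 tested class II peroxidases, the family of manganese and versatile peroxidases, 14 rose and 1 fell on poplar wood (14 and 1 adjusted over the list alone), with a median log2 fold change of 1.68 (camera adjusted p = 1.5e-06, and adjusted p = 0.155 with an estimated correlation). After median-of-ratios scaling 15 rose and 0 fell, and without the intermediate libraries 11 rose and 1 fell. Of 56 hemicellulases and esterases, 11 rose and 1 fell, the same adjusted over the list alone (median 0.30, adjusted p = 0.00084, and adjusted p = 0.386 with an estimated correlation). The endomannanase manA (A16049), which cuts the mannan backbone, was the most abundant that rose, from 491 ± 77.7 to 4540.0 ± 2930.0 FPKM (log2 fold change 2.99, SE 0.41, adjusted p = 0.000151). Among 6 lytic polysaccharide monooxygenases, which cleave cellulose oxidatively, 2 rose and 0 fell (median 0.36, adjusted p = 0.106). One of them, Cel61a (A16833), rose by 1.67 from 107 ± 20.7 to 348 ± 103 FPKM. This list held only genes described as polysaccharide monooxygenase Cel61a, while 4 genes described as Endoglucanase-4 counted as cellulases. The counts therefore hold for that description and not for the whole enzyme class. A16827, with the symbol cel61a, stood at 5.98, 17.7 and 7.44 FPKM in poplar wood replicates 1, 2 and 3. On PDA it stood at 21.6, 22.0 and 19.2 FPKM. Of 15 cellulases, 1 rose and 1 fell, and 0 of either direction without the intermediate libraries (camera adjusted p = 0.106), and of 19 pectin-degrading enzymes 2 rose and 2 fell (adjusted p = 0.111). The exopolygalacturonase PGX1 (A09957) rose by 3.64, from 9.58 ± 3.83 to 131 ± 52.1 FPKM. Of 26 laccases and multicopper oxidases, 5 rose and 5 fell. Their median was -0.47, their mean 0.09 and the direction of their test upward (adjusted p = 0.748). The number that fell was 8 without poplar wood replicate 2 and 3 without the intermediate libraries.

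In central metabolism 16 of 20 glycolysis genes fell and 0 rose (17 and 0 adjusted over the list alone), with a median of -2.07 (adjusted p = 9.77e-06, and adjusted p = 0.386 with an estimated correlation). Triosephosphate isomerase TPI (A14475) went from 538 ± 57.5 to 39.5 ± 26.3 FPKM, a log2 fold change of -4.08, or -3.28 without poplar wood replicate 1. Of 15 genes of fatty acid beta-oxidation 14 fell and 0 rose, the same adjusted over the list alone (median -2.41, adjusted p = 6.89e-09, and adjusted p = 0.155 with an estimated correlation), among them the thiolase POT1 (A08701), which fell by 1.92. With the intermediate libraries left out, 12 glycolysis genes and 14 beta-oxidation genes fell. The beta-oxidation list held 6 genes described as acyl-CoA dehydrogenase AFT10-1 and 4 as acyl-CoA dehydrogenase apdG, so its counts rest largely on these descriptions. Of 15 genes of glyoxylate, oxalate and formate metabolism 6 fell and 0 rose (7 and 1 adjusted over the list alone, median -0.77, adjusted p = 0.204). That list also held genes described as 2-isopropylmalate synthase and 2-methylisocitrate lyase. Of 26 glutathione S-transferases, which conjugate glutathione to reactive compounds, 16 fell and 1 rose (median -1.29, adjusted p = 0.000184, and adjusted p = 0.155 with an estimated correlation). A pair of phosphoketolases (A18876 and A19231), which split sugar phosphates, fell by 5.72 and 5.42 from 177 ± 145 and 137 ± 108 FPKM. Their log2 fold changes were -6.66 and -6.27 without PDA replicate 3 and -5.03 and -4.78 without PDA replicate 1. A gene described as 60S acidic ribosomal protein P2 (A00646), outside the list of cytosolic ribosomal proteins, went from 1060.0 ± 364 to 15.5 ± 6.10 FPKM (adjusted p = 4.58e-07). Of the 80 cytosolic ribosomal proteins in the list none was called, with a median of 0.27, although the list as a whole lay higher than other genes (adjusted p = 0.000828, and adjusted p = 0.77 with an estimated correlation).

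Of 137 transcription factors 3 rose and 28 fell on poplar wood, the same adjusted over the list alone (adjusted p = 0.0555), and 6 rose and 17 fell after median-of-ratios scaling (adjusted p = 0.11). The GATA factor sreA (A08176), named after a repressor of iron uptake, fell by 1.48 from 812 ± 107 to 289 ± 7.34 FPKM. The copper-dependent factor CUF1 (A17766) rose by 1.93 from 19.2 ± 2.06 to 88.6 ± 52.9 FPKM, and by 2.52 without poplar wood replicate 3. Of 161 cytochrome P450s, monooxygenases of varied substrates, 17 rose and 43 fell (adjusted p = 0.451), and 19 rose and 34 fell after scaling. CYP208 (A07914) rose by 3.22 from 95.8 ± 23.0 to 935 ± 365 FPKM.

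Over all genes limma called 3556 on poplar wood against PDA, 1160 higher and 2396 lower, at an adjusted p of 0.05 and an absolute log2 fold change of at least 1. Median-of-ratios scaling moved the median log2 fold change of all tested genes from -0.18 to 0.02 and gave 1576 genes higher and 1764 lower. After this scaling 13 hemicellulases and esterases rose and 1 fell, 15 glycolysis genes and 13 beta-oxidation genes fell and 0 rose, and 13 glutathione S-transferases fell and 1 rose. Every poplar wood library lay above, or every one below, all PDA libraries in 6692 genes (47.9%, against 10% by chance), including each gene named in this comparison except ICL1 (A09090). Without the intermediate libraries 2715 genes were called, 845 higher and 1870 lower, and 2676 of them were among the 3556 with the same sign.

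**Figure D2:**
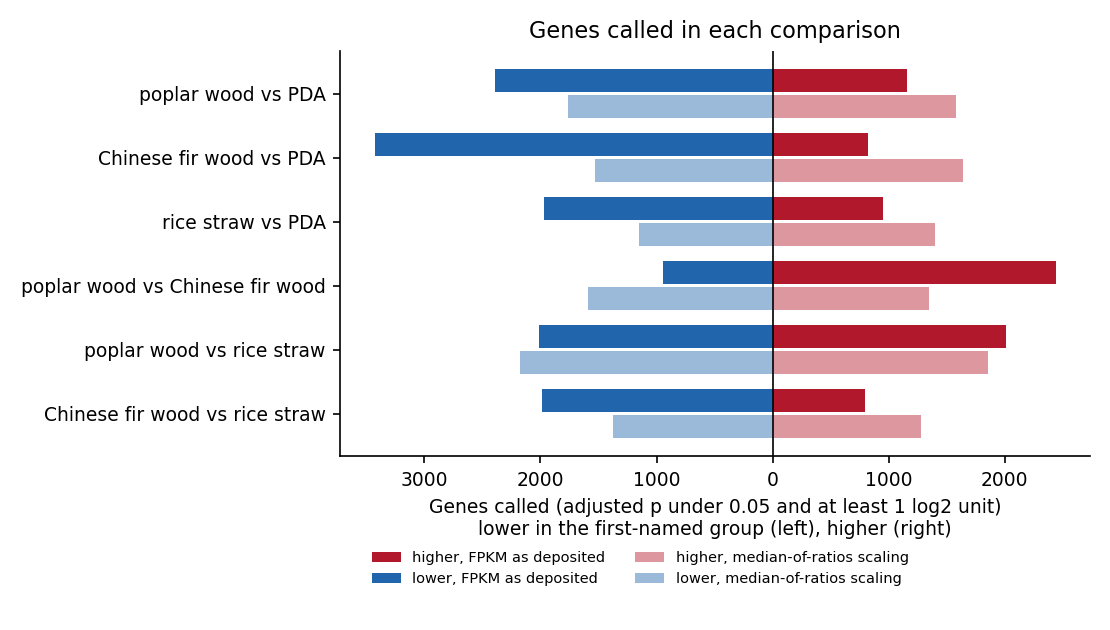
Numbers of genes called higher (to the right) and lower (to the left) in each comparison, from FPKM as deposited and after median-of-ratios scaling. On Chinese fir wood against PDA 826 genes were higher and 3430 lower as deposited, and 1637 higher and 1533 lower after scaling.

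Growth on Chinese fir wood was compared with PDA to describe the response to a softwood. The genes with the largest changes included a laccase and cytochrome P450s that rose, and alcohol oxidases and a formate dehydrogenase that fell. LCC2 (A15469) rose to 367 FPKM (359.35, 444.66 and 297.18 in replicates 1, 2 and 3) from 6.89 ± 3.72 FPKM on PDA (log2 fold change 5.66, SE 0.56, adjusted p = 1.14e-05). CYP208 (A07914) rose by 4.59 to 2312 ± 402 FPKM, and another gene of that name (A07916) rose by 5.83 from 1.19 ± 0.61 to 126 ± 44.0 FPKM. Of the 23 tested genes of this description 5 rose and 10 fell as deposited, the same adjusted over these genes alone, but 6 rose and 3 fell after median-of-ratios scaling. The alcohol oxidases AOD1 (A10974 and A05729), which oxidise methanol and other short alcohols, fell by 6.56 and 6.55. The first of them went from 162 ± 32.5 to 0.709 ± 0.184 FPKM. Formate dehydrogenase FDH1 (A02035) fell by 5.61 from 329 ± 5.96 to 5.80 ± 0.98 FPKM.

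Of 26 laccases and multicopper oxidases 10 rose and 2 fell on Chinese fir wood, the same adjusted over the list alone. The median of the list was -0.19, its mean 0.84 and its test upward (adjusted p = 0.000196, and adjusted p = 0.515 with an estimated correlation). After median-of-ratios scaling 11 rose and 1 fell, with a median of 0.23, and without the intermediate libraries 9 rose and 0 fell. Of 56 hemicellulases and esterases 9 rose and 2 fell, the same adjusted over the list alone (median 0.04, adjusted p = 0.000196, and adjusted p = 0.422 with an estimated correlation). The counts were 14 and 1 after scaling, and 6 and 2 without the intermediate libraries. The endomannanase manA (A16049) rose by 2.03 to 2034 ± 470.0 FPKM. Of 23 class II peroxidases 4 rose and 1 fell (3 and 1 adjusted over the list alone, median 0.37, adjusted p = 0.000289, and adjusted p = 0.422 with an estimated correlation), and 6 rose and 1 fell after scaling. Of 15 cellulases 0 rose and 2 fell (camera adjusted p = 0.0973), and 0 of either direction were called after scaling. The lactose permease LAC12 (A12161), a sugar transporter by name, rose by 4.59 from 19.5 ± 1.54 to 493 ± 55.3 FPKM.

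Of 15 genes of fatty acid beta-oxidation 13 fell and 0 rose on Chinese fir wood, the same adjusted over the list alone and without the intermediate libraries (median -2.09, adjusted p = 6.37e-06, and adjusted p = 0.422 with an estimated correlation). After scaling 11 fell. The malate synthase acuE (A01812) fell by 3.34, while the isocitrate lyase ICL1 (A09090) rose by 1.40 to 1831 ± 451 FPKM (adjusted p = 0.0153). That call was lost without Chinese fir wood replicate 2 (adjusted p = 0.0581), without the intermediate libraries (adjusted p = 0.121) and after quantile normalisation (adjusted p = 0.0723). The rise was not shared by ACU-7 (A18288) and a second gene named ICL1 (A06133), given here after their values were seen. ACU-7 stood at 138, 120 and 152 FPKM in replicates 1, 2 and 3, against 968, 1038 and 1119 on PDA. A06133 stood at 7.23, 10.3 and 8.36 FPKM, against 130, 248 and 345 on PDA. Of 15 genes of glyoxylate, oxalate and formate metabolism 1 rose and 7 fell, the same adjusted over the list alone (adjusted p = 0.271). In the list of 40 ABC transporters, which also held 9 factors that regulate them and that are counted among the transcription factors too, 16 fell and 0 rose (17 and 0 adjusted over the list alone, adjusted p = 0.00586, and adjusted p = 0.544 with an estimated correlation), and 10 fell after scaling. Without these factors 11 of 31 fell (12 adjusted over these genes alone). Of 137 transcription factors 4 rose and 51 fell, the same adjusted over the list alone (median -0.80, adjusted p = 0.0414, and adjusted p = 0.422 with an estimated correlation). After scaling 13 rose and 21 fell (adjusted p = 0.0788). The list's call was lost without the intermediate libraries (0.0579), PDA replicate 1 (0.061), Chinese fir wood replicate 3 (0.0562), poplar wood replicate 1 (0.0515) and poplar wood replicate 3 (0.0511), each value an adjusted p. The pH-response factor RIM101 (A04452) fell by 3.75 from 1501 ± 82.7 to 111 ± 8.70 FPKM, and CTF1-ALPHA (A09445), a factor named after the regulator of cutinase genes, rose by 1.74 from 57.7 ± 4.58 to 195 ± 8.57 FPKM.

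Of 76 genes of oxidative phosphorylation 7 rose and 4 fell on Chinese fir wood, the same adjusted over the list alone (median 0.48, adjusted p = 2.21e-09, and adjusted p = 0.671 with an estimated correlation). After scaling 40 rose and 0 fell (median 1.07, adjusted p = 2.95e-10). The number that rose was 26 without Chinese fir wood replicate 2, 15 without PDA replicate 1, 1 without Chinese fir wood replicate 3 and 2 without the intermediate libraries, where 0 fell. The cytochrome oxidase subunit cox12 (A01679) rose by 1.37 from 444 ± 88.6 to 1136 ± 128 FPKM. Of 80 cytosolic ribosomal proteins 37 fell and 0 rose, the same adjusted over the list alone (median -0.99, adjusted p = 0.000726, and adjusted p = 0.692 with an estimated correlation). After scaling limma called 0 of them (median -0.41, camera adjusted p = 0.00417). The number that fell was 59 without PDA replicate 1, 16 without PDA replicate 3, 16 without Chinese fir wood replicate 2 and 3 without the intermediate libraries. Of 161 cytochrome P450s 15 rose and 44 fell (15 and 43 adjusted over the list alone), and 22 rose and 22 fell after scaling. Their median was -0.41 as deposited and 0.05 after scaling, and their test pointed upward (adjusted p = 0.473).

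Over all genes limma called 4256 on Chinese fir wood against PDA, 826 higher and 3430 lower. Median-of-ratios scaling moved the median log2 fold change of all tested genes from -0.51 to -0.02 and gave 1637 genes higher and 1533 lower. Of the 4256 genes, 2359 were called with the same sign after scaling. The directions above are those of the deposited values unless scaling is named. The 10 most abundant genes held up to 11.4% of the reads on Chinese fir wood and up to 5.23% on PDA. Groups did not overlap in 9908 genes (70.9%, against 10% by chance), including each gene named in this comparison, and 2873 genes were called without the intermediate libraries, 554 higher and 2319 lower.

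Growth on rice straw was compared with PDA to describe the response to a grass. Xylanases and genes named as endoglucanases were among the genes with the largest rises. The xylanase xlnB (A02231) went from 1.62 ± 1.09 to 308 ± 89.2 FPKM, a log2 fold change of 6.92 (SE 0.69, adjusted p = 2.05e-05), and the xylanase xynD (A04146) rose by 4.96. The genes eglB (A09810) and eglD (A14936), endoglucanases by name, each rose by 4.50. Genes entered the lists by description, so these need not be members of the list of cellulases below. The acetylxylan esterase axeA (A15964) rose by 4.27. The laccase LCC2 of locus A06358 fell by 4.56, from 174 ± 41.7 to 6.35 ± 1.09 FPKM.

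Of 56 hemicellulases and esterases 30 rose and 1 fell on rice straw, the same adjusted over the list alone (mean log2 fold change 1.47, adjusted p = 3.54e-17, and adjusted p = 0.0298 with an estimated correlation). The counts were 23 and 1 without the intermediate libraries. Of 15 cellulases 8 rose and 1 fell, the same adjusted over the list alone (median 1.65, adjusted p = 2.02e-05, and adjusted p = 0.104 with an estimated correlation). The exoglucanase cel3 (A15830), which releases cellobiose from cellulose, rose by 3.90 from 5.56 ± 0.63 to 97.2 ± 11.6 FPKM. Of 19 pectin-degrading enzymes 6 rose and 0 fell (median 0.71, adjusted p = 1.32e-05, and adjusted p = 0.0298 with an estimated correlation), among them PGX1 (A09957), which rose by 3.03. Of 28 beta-glucosidases 8 rose and 1 fell (median 0.55, adjusted p = 0.000189, and adjusted p = 0.104 with an estimated correlation). This list also held glucan 1,3-beta-glucosidases, which act on fungal cell walls, and shared 16 members with the list of chitinases and beta-1,3-glucanases. The beta-glucosidase bglL (A17008) rose by 3.08 from 12.6 ± 0.26 to 115 ± 13.1 FPKM. Of 15 GMC oxidoreductases, flavoenzymes that include producers of hydrogen peroxide, 5 rose and 0 fell (median 0.67, adjusted p = 0.000541, and adjusted p = 0.0313 with an estimated correlation), but 1 rose without the intermediate libraries.

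Of 22 sugar transporters 8 rose and 2 fell on rice straw (median 0.16, adjusted p = 0.00504, and adjusted p = 0.217 with an estimated correlation), and 8 and 1 without the intermediate libraries. Genes of the name LAC12 rose by 4.59 (A19119) and by 3.32 (A09461). Of 30 cell wall synthesis genes 7 rose and 2 fell (median 0.20, adjusted p = 0.00129, and adjusted p = 0.0313 with an estimated correlation), or 5 and 0 without the intermediate libraries, with the chitin synthase regulator CSR2 (A17143) higher by 2.13. Of 41 heat shock proteins and chaperones 14 rose and 3 fell (median 0.50, adjusted p = 0.000648, and adjusted p = 0.491 with an estimated correlation). The number that rose was 9 without rice straw replicate 2, 9 without rice straw replicate 3 and 6 without the intermediate libraries, where 1 fell. Class II peroxidases had 3 members that rose and 2 that fell of 23 (median 0.54, adjusted p = 0.0113, and adjusted p = 0.369 with an estimated correlation), and the list was no longer called after scaling (adjusted p = 0.0724). Leaving out the intermediate libraries, 1 rose and 0 fell. Of 26 laccases and multicopper oxidases 7 rose and 4 fell, with a median of -0.35, a mean of -0.20 and an upward test (adjusted p = 0.403), and 7 fell without PDA replicate 3. The laccase LCC4 (A17335) rose by 1.95.

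Of 26 glutathione S-transferases 13 fell and 0 rose on rice straw (median -0.97, adjusted p = 0.00292, and adjusted p = 0.104 with an estimated correlation), and 8 fell without the intermediate libraries. In the list of 40 ABC transporters and their 9 regulating transcription factors together 16 fell and 0 rose (median -0.73, adjusted p = 0.000541, and adjusted p = 0.217 with an estimated correlation), and 11 of 31 fell without these factors. Of 15 beta-oxidation genes 11 fell and 0 rose (median -1.43, adjusted p = 7.72e-05, and adjusted p = 0.203 with an estimated correlation), including the acyl-CoA dehydrogenase AFT10-1 (A03131), which fell by 1.83 from 1079 ± 34.6 to 303 ± 35.7 FPKM. Leaving out the intermediate libraries, 7 of them fell. Of 137 transcription factors 7 rose and 29 fell (7 and 30 adjusted over the list alone, median -0.48, adjusted p = 0.0151, and adjusted p = 0.203 with an estimated correlation). The factor sreA (A08176) rose by 1.21 to 1870.0 ± 199 FPKM, the opposite of its direction on poplar wood. The dehydroshikimate dehydratase qa-4 (A16425), an enzyme of quinate breakdown, fell by 6.35 from 329 ± 78.8 FPKM.

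Over all genes limma called 2923 on rice straw against PDA, 952 higher and 1971 lower. Scaling moved the median log2 fold change of all tested genes from -0.25 to -0.01 and gave 1397 genes higher and 1153 lower. After scaling 35 hemicellulases and esterases rose and 1 fell, 8 cellulases and 7 pectin-degrading enzymes rose and 0 fell, 11 glutathione S-transferases fell and 2 rose, 8 beta-oxidation genes fell and 0 rose, and 12 transcription factors rose and 21 fell. Groups did not overlap in 9059 genes (64.8%, against 10% by chance), including each gene named in this comparison. Without the intermediate libraries 1446 genes were called, 484 higher and 962 lower, and 1427 of them were among the 2923 with the same sign.

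**Figure D3:**
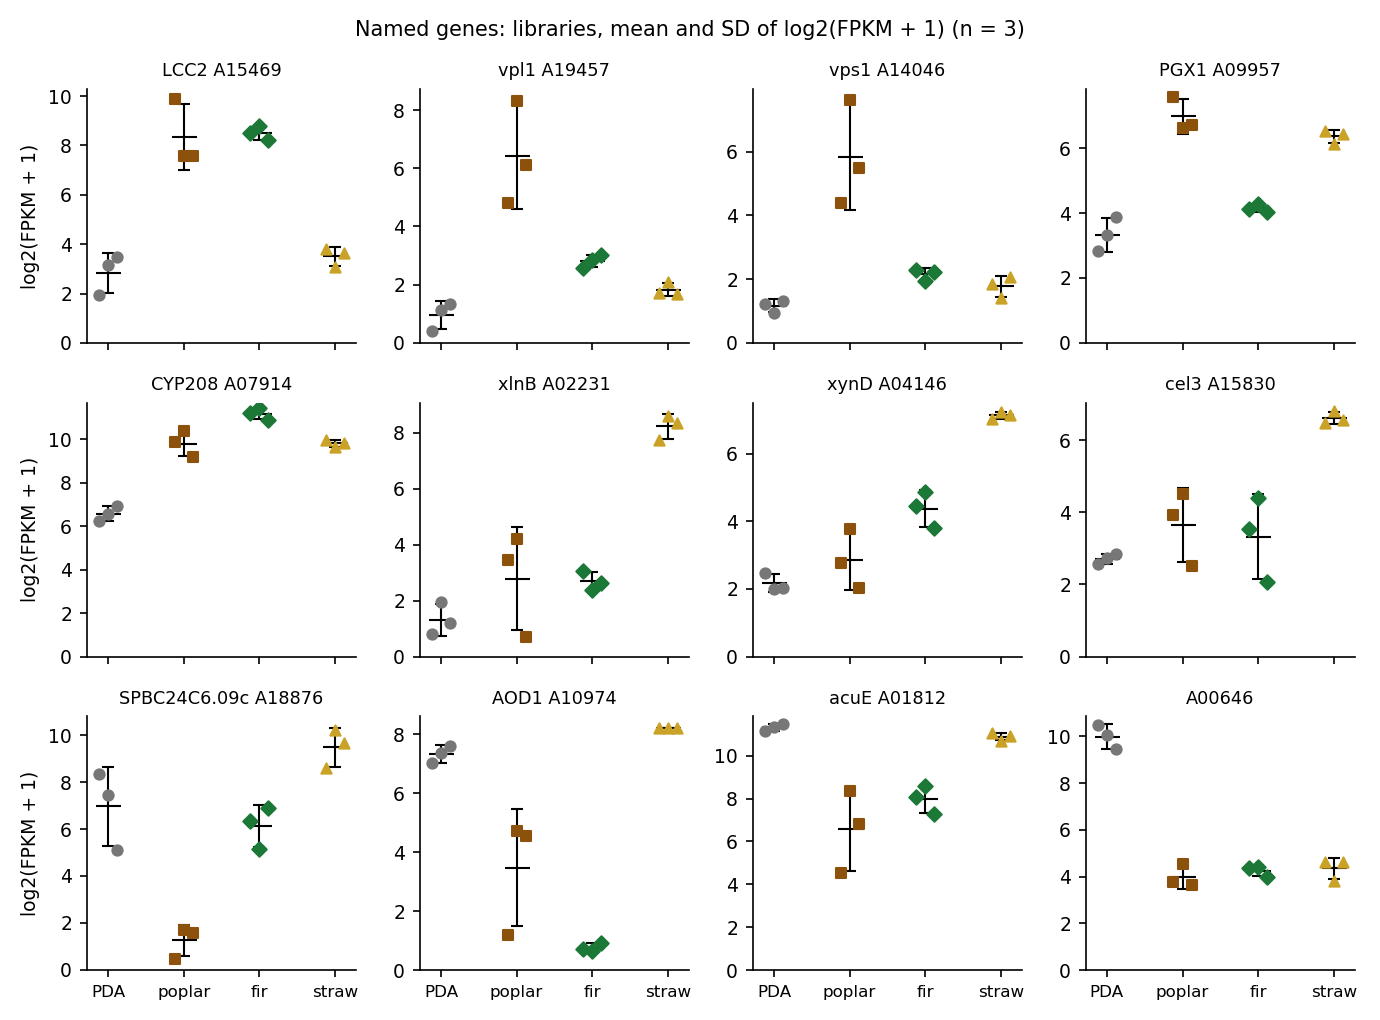
Expression of 12 named genes as log2(FPKM + 1) in each library (points), with the group mean (line) and SD (bar, n = 3). LCC2 (A15469) is high on both woods, xlnB (A02231) on rice straw and acuE (A01812) on PDA and rice straw.

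The responses to the 3 substrates were compared to find the part they had in common. Every response is a difference from PDA, the only control medium. A change in common may therefore come from growth on PDA or from growth on plant material, which cannot be told apart here. Of 6672 genes called against PDA on any substrate, 962 were called on all 3, and 872 of these had the same direction in each. The number higher on all 3 was 165, against 4.67 for independent lists, and the number lower was 707, against 82.9. Both counts were 0 in simulations of unchanged groups that shared the PDA libraries. Unchanged genes are rarely called at all, so these simulations do not measure how much overlap shared controls add among genes that changed. Genes called in 1 comparison alone numbered 1203 on poplar wood, 1496 on Chinese fir wood and 872 on rice straw, and differences between substrates are tested directly below. The number with the same direction on all 3 was 500 without the intermediate libraries.

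Among the genes higher on all 3 substrates were CYP208 (A07914), with a log2 fold change of 3.68 for the mean of the substrates against PDA (SE 0.23, adjusted p = 5.71e-07), and the fruiting body protein SC3 (A09953), a hydrophobin that coats aerial hyphae, with 3.35 (SE 0.34, adjusted p = 1.53e-05). A GPI-anchored cupredoxin (A12831) had 4.29 (SE 0.69, adjusted p = 0.000416), but its calls on Chinese fir wood and rice straw were lost without the intermediate libraries. Among those lower on all 3 were A00646 (-5.79, adjusted p = 1.56e-07), the FAD-dependent monooxygenase dbaH (A04413, -5.35, adjusted p = 2.86e-07) and the isomerases YHI9 (A08715, -4.41, adjusted p = 2.21e-07, and A16960, -4.30, adjusted p = 1.74e-08). ATG8 (A12834), a protein of autophagosome membranes, fell by 2.54 on poplar wood, 2.20 on Chinese fir wood and 1.56 on rice straw.

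Against PDA, 357 genes were higher on both woods (independent lists 68.6) and 1578 lower (588), with 77 in opposite directions. Poplar wood and rice straw shared 246 higher (79.0) and 829 lower (338), with 228 opposite, and Chinese fir wood and rice straw shared 338 higher (56.3) and 1277 lower (484), with 95 opposite. Across genes, which are not independent replicates, the log2 fold changes of the 2 woods correlated at 0.609, those of poplar wood and rice straw at 0.358, and those of Chinese fir wood and rice straw at 0.585. Shared control libraries alone gave 0.50 in the simulation. The covariances were 0.70, 0.36 and 0.60, each against a simulated 0.05, which left 0.65, 0.32 and 0.56. The 3 PDA libraries could not be split into parts of at least 2, so part of the excess over independent lists may come from the shared controls.

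The 2 woods, a single hardwood and a single softwood, were compared directly. On poplar wood VPL1 (A19457) was higher by 3.59 (SE 0.65, adjusted p = 0.00112), at 138 ± 159 FPKM against 6.08 ± 1.02 FPKM, and Cel61a (A16833) by 2.04, at 348 ± 103 against 81.5 ± 0.42 FPKM. PGX1 (A09957) was higher by 2.83. The log2 fold change of VPL1 was 4.40 without poplar wood replicate 1 and 2.63 without replicate 2. On Chinese fir wood the GH30 xylanase Xyn30A (A02045) was higher, with a log2 fold change of -2.32 for poplar wood against Chinese fir wood (adjusted p = 5.95e-06) and 281 ± 3.37 FPKM against 55.7 ± 5.86 FPKM. The pectinesterase pme1 (A07668), which removes methyl groups from pectin, had -2.51, and the laccase LCC4 (A17335) had -1.18, at 165 ± 11.7 against 73.7 ± 18.8 FPKM.

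In this comparison of poplar wood with Chinese fir wood, 11 of 23 class II peroxidases were higher and 0 lower, the same adjusted over the list alone (median 0.88, adjusted p = 0.0637), and 7 were higher after scaling (adjusted p = 0.0166), 7 without poplar wood replicate 2 and 4 without the intermediate libraries. Of 6 lytic polysaccharide monooxygenases 3 were higher and 0 lower (median 1.10, adjusted p = 0.0407, and adjusted p = 0.728 with an estimated correlation), a call lost without poplar wood replicate 1 (adjusted p = 0.152) or Chinese fir wood replicate 2 (adjusted p = 0.0563). Of 26 laccases and multicopper oxidases 1 was higher and 7 lower (median -0.42, adjusted p = 0.000326, and adjusted p = 0.728 with an estimated correlation). That call was lost without poplar wood replicate 3 (adjusted p = 0.0501). After scaling 1 was higher and 8 lower. Hemicellulases and esterases had 9 higher and 4 lower of 56 (median 0.25, mean 0.34, test downward, adjusted p = 0.999), and 6 higher and 6 lower after scaling.

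Of 80 cytosolic ribosomal proteins 59 were higher on poplar wood than on Chinese fir wood and 0 lower, the same adjusted over the list alone (median 1.25, adjusted p = 1.94e-10, and adjusted p = 0.728 with an estimated correlation). After scaling 27 were higher (median 0.89, adjusted p = 1.62e-12). RPL19A (A04308), a protein of the large subunit, was higher by 1.46. Leaving out the intermediate libraries gave 36 higher. Of 76 genes of oxidative phosphorylation 4 were higher and 20 lower (median -0.49, adjusted p = 1.86e-08, and adjusted p = 0.728 with an estimated correlation), and 34 were lower after scaling. The number lower was 32 without Chinese fir wood replicate 2, 30 without poplar wood replicate 3 and 13 without the intermediate libraries, and the number higher was 1 without the intermediate libraries and 2 without any 1 of poplar wood replicate 2, poplar wood replicate 3, Chinese fir wood replicate 1 and Chinese fir wood replicate 2. The subunit cox12 (A01679) had -1.79. Of 20 glycolysis genes 8 were lower and 1 higher (median -0.55, adjusted p = 0.00106, and adjusted p = 0.728 with an estimated correlation), and 5 were lower without Chinese fir wood replicate 3 and 4 without the intermediate libraries. In all, limma called 3380 genes, 2439 higher and 941 lower, and 1346 higher and 1591 lower after scaling, which moved the median of all tested genes from 0.30 to 0.01. Groups did not overlap in 6214 genes (44.5%, against 10% by chance). Without the intermediate libraries 2377 genes were called, 1716 higher and 661 lower.

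Poplar wood was compared with rice straw, the single grass material. LCC2 (A15469) was higher on poplar wood by 4.84 (SE 0.56, adjusted p = 3.94e-05) and VPL1 (A19457) by 4.59 (SE 0.65, adjusted p = 0.000148). The cytochrome P450s FG08079 (A18116 and A03184) were higher by 6.08 and 5.80. The phosphoketolases (A18876 and A19231) were lower on poplar wood, with log2 fold changes of -8.26 and -8.10, and stood at 1.52 ± 0.99 and 1.47 ± 0.77 FPKM there against 797 ± 403 and 716 ± 350.0 FPKM on rice straw. The xylanase xlnB (A02231) had -5.44 and the exoglucanase cel3 (A15830) -2.97. Leaving out poplar wood replicate 1 gave 4.07 for LCC2 and 5.40 for VPL1, leaving out replicate 2 gave 3.63 for VPL1 and -6.15 for xlnB, and leaving out replicate 3 gave -4.40 for xlnB. The laccase LCC5 (A13006) had -4.66, and the manganese superoxide dismutase A02697, which removes superoxide in mitochondria, had -4.47.

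Of 56 hemicellulases and esterases 2 were higher on poplar wood than on rice straw and 24 lower, the same adjusted over the list alone (median -0.76, adjusted p = 0.000236, and adjusted p = 0.541 with an estimated correlation). Of 15 cellulases 1 was higher and 7 lower (median -0.96, adjusted p = 0.009, and adjusted p = 0.577 with an estimated correlation). Of 22 sugar transporters 10 were lower and 0 higher (median -0.63, adjusted p = 0.00543, and adjusted p = 0.541 with an estimated correlation). Of 23 class II peroxidases 12 were higher and 1 lower (13 and 1 adjusted over the list alone, median 1.23, adjusted p = 0.0142, and adjusted p = 0.721 with an estimated correlation), a call lost without poplar wood replicate 1 (adjusted p = 0.0686). Of 15 beta-oxidation genes 7 were lower and 0 higher (median -0.93, adjusted p = 0.000411, and adjusted p = 0.541 with an estimated correlation). Limma called 4025 genes, 2008 higher and 2017 lower, and 1857 higher and 2179 lower after scaling. Groups did not overlap in 6942 genes (49.7%, against 10% by chance), and 3191 genes were called without the intermediate libraries.

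Chinese fir wood was compared with rice straw in the same way. LCC2 was higher on Chinese fir wood at both A15469 (367 against 10.6 FPKM, SE of the log2 fold change 0.56, adjusted p = 5.4e-05) and A06358 (log2 fold change 4.64, SE 0.66, adjusted p = 0.000276), and CYP208 (A07916) was higher by 5.62. The alcohol oxidases AOD1 (A10974 and A05729) had -7.45 and -7.29, the pyranose dehydrogenase pdh1 (A17479), an oxidoreductase of sugars, -3.68, and the iron multicopper oxidase fer1 (A04976) -3.29. The small heat shock protein hsp16 (A00935), a chaperone, had -5.41, at 22.4 ± 7.52 against 965 ± 21.2 FPKM.

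Of 56 hemicellulases and esterases 2 were higher on Chinese fir wood than on rice straw and 30 lower, the same adjusted over the list alone (median -1.06, adjusted p = 2.4e-05, and adjusted p = 0.31 with an estimated correlation). After scaling 3 were higher and 25 lower, and without the intermediate libraries 1 and 20. Xyn30A (A02045) was one of the higher members, by 2.35. Of 19 pectin-degrading enzymes 1 was higher and 10 lower (median -1.02, adjusted p = 0.0012, and adjusted p = 0.208 with an estimated correlation), and of 22 sugar transporters 1 was higher and 12 lower (median -1.25, adjusted p = 2.4e-05, and adjusted p = 0.208 with an estimated correlation). Of 15 cellulases 8 were lower and 0 higher (median -1.47, adjusted p = 0.0102, and adjusted p = 0.545 with an estimated correlation), a call lost without poplar wood replicate 1 (adjusted p = 0.062), which entered the shared estimate of spread. Of 26 laccases and multicopper oxidases 9 were higher and 3 lower (median 0.59, adjusted p = 8.37e-05, and adjusted p = 0.525 with an estimated correlation), and 8 and 1 without the intermediate libraries. Limma called 2781 genes, 797 higher and 1984 lower, and 1281 higher and 1372 lower after scaling, which moved the median of all tested genes from -0.23 to 0.02. After scaling 8 pectin-degrading enzymes were lower and 1 higher, 11 sugar transporters lower and 1 higher and 8 cellulases lower and 0 higher, and 11 laccases and multicopper oxidases were higher and 3 lower. Groups did not overlap in 8186 genes (58.6%, against 10% by chance). Without the intermediate libraries 1392 genes were called, 350 higher and 1042 lower.

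The summed FPKM of each enzyme class gave its part of the measured expression. Hemicellulases and esterases summed to 824 ± 104 FPKM on PDA, 5239 ± 3080.0 on poplar wood, 2651 ± 506 on Chinese fir wood and 2598 ± 285 on rice straw, higher in 9 of 9 substrate libraries than in any PDA library (two-sided exact permutation test of 9 against 3 libraries, p = 0.0409, adjusted p = 0.184). The endomannanase manA (A16049) made up 4540.0 of the 5239 FPKM on poplar wood and 2034 of the 2651 on Chinese fir wood. Without it the sums were 333 ± 26.2 on PDA, 699 ± 162 on poplar wood, 617 (576.7 to 649.5) on Chinese fir wood and 1424 ± 31.9 on rice straw (exact p = 0.0273, adjusted p = 0.109), with rice straw and not poplar wood the highest. Laccases and multicopper oxidases summed to 687 ± 2.93 FPKM on PDA, 1640.0 ± 1340.0 on poplar wood, 1953 ± 424 on Chinese fir wood and 442 ± 9.19 on rice straw (exact p = 0.309). On poplar wood the mean was 878 without replicate 1, and the sum of replicate 3, 654.3 FPKM, lay below every PDA library. Class II peroxidases summed to 64.0 ± 9.06, 505 ± 446, 94.7 ± 7.31 and 72.9 ± 11.1 FPKM (exact p = 0.273), with a mean of 249.7 on poplar wood without replicate 2. Cellulases summed to 82.4 ± 2.95, 96.0 ± 28.8, 60.8 ± 13.4 and 256 ± 23.0 FPKM (exact p = 0.377). The single dye-decolorizing peroxidase (A14508), an enzyme that oxidises dyes and phenols, stood at 48.3 ± 20.5, 9.97 ± 6.93, 4.25 ± 1.01 and 28.2 ± 4.90 FPKM, lower in 7 of 9 substrate libraries than in any PDA library (exact p = 0.0136, adjusted p = 0.123), with a mean of 6.15 on poplar wood without replicate 3. After adjustment over the 9 sums 0 differed between substrates and PDA by the exact permutation test, and 2 did at an unadjusted p of 0.05. The smallest p of this test was 0.00455, and 3 libraries against 3 could not go below 0.1.

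**Figure D4:**
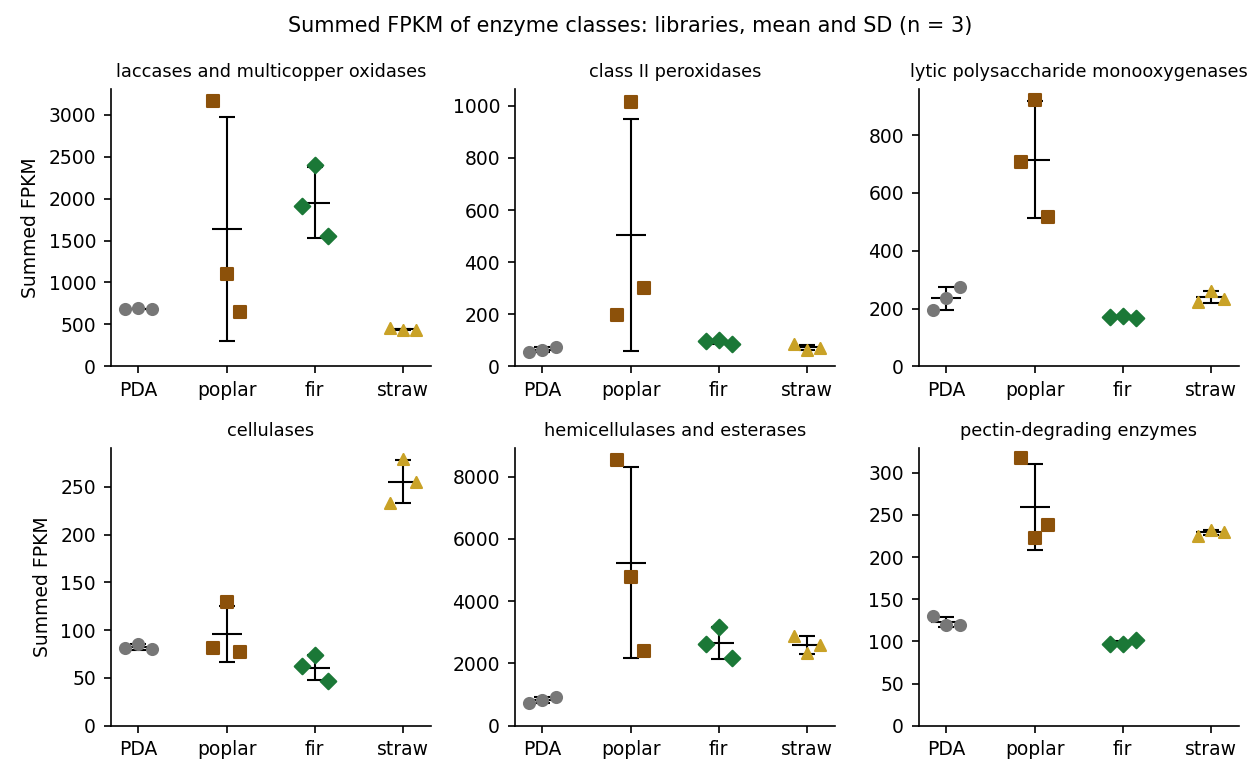
Summed FPKM of 6 enzyme classes in each library (points), with the mean and SD of each group (n = 3). Hemicellulases and esterases are higher in 9 of 9 substrate libraries than on PDA, with manA the larger part on both woods, and cellulases average 256 FPKM on rice straw against 82.4 on PDA.

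Genes that share a name, as among the class II peroxidases, the laccases LCC2 and the pairs AOD1, FG08079 and phosphoketolase, were not compared in sequence. How reads that fit more than 1 of them were counted is not given in the sources used here, so the single values of such genes are uncertain. The call of every gene named above as called was kept under every alternative setting tried, except for the cupredoxin A12831 and ICL1 (A09090) on Chinese fir wood as stated and for sreA on rice straw, where quantile normalisation gave a log2 fold change of 0.95.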

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

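Of 256 alternative values for 16 results, 231 stayed within 1.5 times and 25 moved. With a pseudocount of 5 the genes called were 2338, 2512 and 1858 for poplar wood, for Chinese fir wood and for rice straw against PDA, 2029 for poplar wood against Chinese fir wood, 2633 for poplar wood against rice straw, 1680 for Chinese fir wood against rice straw, and 1649 for the 3 substrates against PDA. A larger pseudocount shrinks fold changes by construction. With no fold threshold the numbers were, in that order, 5809, 7105, 5140, 5753, 6538, 4651 and 5917. Leaving out each library in turn gave ranges of 3236 to 4103, 3948 to 4137, 2452 to 2940, 3000 to 4321, 3788 to 4368, 2433 to 2780 and 2447 to 2867.

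With an estimated correlation camera called 0, 0, 4, 0, 0 and 0 lists in the 6 comparisons, against 9, 9, 15, 7, 8 and 8. Leaving out each library gave 9 to 15, 8 to 9, 14 to 16, 6 to 9, 6 to 11 and 7 to 10, with 15 for poplar wood against PDA without poplar wood replicate 3. The cause was not tested.

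Leaving out the intermediate libraries gave 1446 genes for rice straw against PDA, 1392 for Chinese fir wood against rice straw, 5559 differing among the 4 groups and 500 of the same direction on all 3 substrates. Leaving out each library in turn gave 9194 to 11641 and 777 to 965 for the last 2. Replicate number as a block gave 3564, 4267, 2939, 3392, 4047, 2789 and 2619 genes, 10260 by the F test, and 9, 8, 15, 8, 8 and 8 lists, losing the transcription factors on Chinese fir wood against PDA (adjusted p = 0.0537), although 4 of 12 libraries correlated best with their own number. Of 7785 values for 410 calls of named genes, 7235 stayed called, 550 were weaker and 0 reversed. Voom and the omission of intermediate libraries were chosen after seeing the data.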

Other observations

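Gene groups by the pathway names given with the genes were tested as well, 97 pathways in each comparison, and these tests were chosen after seeing the data. Only some of the called pathways are described here. Of 80 genes of ribosome biogenesis 37 rose and 5 fell on poplar wood against PDA (median 0.90, adjusted p = 1.93e-08, and adjusted p = 0.774 with an estimated correlation), and 43 rose and 5 fell after median-of-ratios scaling. Against rice straw 51 were higher on poplar wood and 0 lower (median 1.88, adjusted p = 5.32e-13, and adjusted p = 0.581 with an estimated correlation), and against Chinese fir wood 52 were higher and 0 lower (median 1.71, adjusted p = 6.94e-10, and adjusted p = 0.863 with an estimated correlation), with 50 and 48 higher and 0 lower after scaling. On rice straw against PDA 1 of these genes rose and 30 fell (median -0.87, adjusted p = 0.000335, and adjusted p = 0.977 with an estimated correlation), and 1 rose and 15 fell after scaling. The pathway was not called on Chinese fir wood against PDA. Of 35 genes of fatty acid degradation 23 fell and 0 rose on poplar wood against PDA (median -2.11, adjusted p = 9.43e-08, and adjusted p = 0.0153 with an estimated correlation), and 19 fell and 0 rose on Chinese fir wood (median -1.40, adjusted p = 0.0129, and adjusted p = 0.476 with an estimated correlation). After scaling 22 fell and 0 rose on poplar wood, and 15 fell and 1 rose on Chinese fir wood. Fatty acid degradation was not called on rice straw against PDA. Against rice straw 3 were higher and 20 lower on poplar wood (median -1.15, adjusted p = 1.03e-05, and adjusted p = 0.0442 with an estimated correlation). On Chinese fir wood against rice straw 2 were higher and 14 lower (median -0.88, adjusted p = 0.043, and adjusted p = 0.494 with an estimated correlation). Of 88 peroxisome genes 39 fell and 4 rose on poplar wood (median -0.88, adjusted p = 1.78e-05, and adjusted p = 0.232 with an estimated correlation), 43 fell and 3 rose on Chinese fir wood (median -1.09, adjusted p = 0.0456, and adjusted p = 0.962 with an estimated correlation), and 29 fell and 3 rose on rice straw (median -0.69, adjusted p = 0.00761, and adjusted p = 0.722 with an estimated correlation). After scaling 32 peroxisome genes fell and 4 rose on poplar wood, 28 fell and 6 rose on Chinese fir wood (median -0.55), and 20 fell and 5 rose on rice straw.

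Other splits of the libraries of a comparison were counted to see how often unlike groups give as many calls; these counts were planned. Between 2 groups of 3, only 10 splits exist and a share under 0.05 cannot be reached. The real split was the only 1 of 10 with as many genes called in each of the 6 comparisons, with 3556, 4256, 2923, 3380, 4025 and 2781 against a highest other count of 0, 0, 1, 1, 1 and 0. For gene lists, 4, 5, 1, 5, 2 and 3 of 10 splits, the real one included, gave as many as the real 9, 9, 15, 7, 8 and 8, and the highest other counts were 13, 11, 14, 11, 9 and 10. Of 100 splits of the 12 libraries, the real one included, only 1 gave as many genes as the real one for the 3 substrates against PDA (2626, highest other 1729), only 1 for the F test (10338, highest other 869) and only 1 for the overlap (872, highest other 562).

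Pattern A is that Chinese fir wood replicate 1, rice straw replicate 3 and PDA replicate 2 lay near the mean of their group mates; the tests of pooled reads and mixed RNA were chosen after seeing the result. Pooling of the mates' reads is excluded, because the smallest chi-square per gene was 4.92, far above the value of 1 for resampled reads. Mixed RNA of the mates has the value it needs, since the weights of the mates summed to 0.985, 1.015 and 0.982 on the linear scale in genes that differed between them, where a mean of logs would give 0.709, 0.711 and 0.684. Such a sum alone does not single out a mixture, since poplar wood replicate 3 gave 0.965 with weights of -0.111 and 1.075 and a chi-square per gene of 197. The chi-square values were not set against mixed RNA, because the spread between libraries made from the same RNA was not measured. A separate culture that was truly intermediate stays open. Poplar wood replicate 2 also lay between its mates in 57.5% of genes, the same share as rice straw replicate 3. Its chi-square per gene was 151 and its weights summed to 0.715, where a mean of logs would give 0.685. A library can thus lie between its mates without being close to a linear mixture of them. Poplar wood replicate 2 was kept when the intermediate libraries were left out. If the 3 intermediate libraries were mixtures, their groups could have 2 independent cultures each, and the calls without these 3 libraries would be the ones to use.

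Pattern B is that poplar wood replicate 1 correlated more with 2 Chinese fir wood libraries (0.877 and 0.897) than with poplar wood replicate 3 (0.865), although its highest correlation was with poplar wood replicate 2 (0.926) and that with Chinese fir wood replicate 3 was 0.849; both tests were chosen after seeing the result. Chinese fir wood RNA or reads stay open, because a mixture fit gave shares of 10.7 to 23.9% by the library taken as source but a chi-square per gene of 353.9 to 365.1, no lower than the 353.7 without Chinese fir wood, so the share was not defined. Of 3779 genes at 20 FPKM or more in every Chinese fir wood library, 44 stood in poplar wood replicate 1 below the lowest of these shares of their lowest Chinese fir wood level, and 17 (0.45%) below 0.5 of it, which decides nothing without a defined share. Differences between the cultures stay open too and were not tested. Exchanged labels with a Chinese fir wood library are excluded, because the lowest correlation among Chinese fir wood libraries, 0.967, was 0.07 above the highest of them with a poplar wood library.

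Pattern C is that more genes were called lower than higher on Chinese fir wood against PDA, and its test was chosen after seeing the result. The 10 most abundant genes held 11.2% of the reads on Chinese fir wood and 5.0% on PDA, which lowers all other genes by 0.098 on the log2 scale (a shift of -0.098, -0.105 to -0.091 over pairs of libraries). This excludes these few genes as the whole cause, because the median of all genes moved by -0.4887 relative to median-of-ratios scaling. The 100 most abundant genes give -0.258 and the 1000 most abundant -0.506, so a shift of reads to many abundant genes stays open, as does a fall in most genes. The 51.64% of called genes that were higher after scaling decide nothing, because that scaling centres the fold changes.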
